A study of Homo sapiens with 6 samples.

How the data were processed

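Total RNA from 3 glioma cell lines, each with HOTAIRM1 knockdown or a control hairpin, was labelled with Cy3 and hybridised to 6 human long non-coding RNA arrays of 180880 spots. The samples were grouped by the titles and the cell line named in the labels. U87MG is replicate 1, T98G replicate 2 and A172 replicate 3 of each group.

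The deposited files hold spot intensity values on a linear scale from Agilent Feature Extraction, version 11.5.1.1 per the file headers and 10.7 per the submitters' processing notes. The processed signal is the authors' background-corrected intensity, and its median differed between arrays. The median spot signal and the median local background are also deposited intensity values. The flags for well above background, non-uniform outlier and saturated spots were deposited beside them. The array grid refers to hg19 per the file headers. The series design names quantile normalization in GeneSpring 11.0 per the labels, and for that reason quantile normalization was used here.

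From these files, log2 of the processed signal was taken over 175906 non-control spots, outlier spots were set to missing (18 to 61 per array), arrays were quantile normalized, and the 2 to 5 spots of each of 71816 probes were averaged. No non-control spot was flagged as saturated, and control spots were left out of that count. A probe counted as above background on an array when at least 50% of its spots carried the flag, and 57367 probes (79.9%) above background on at least 3 of the 6 arrays were kept. The SD between spots of one probe was 0.345 to 0.435 on the log2 scale. Differences were tested with limma 3.58.1 in R 4.3.3, with cell line as a block, moderated variances and Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual and 3.94 prior degrees of freedom. Counts of probes at least 2-fold apart in a line used probes above background on at least 1 of its 2 arrays.

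The block rests on the design, in which each line has a knockdown and a control version. Deviations from the group means correlated within pairs at 0.849, 0.82 and 0.774, and the fit with no replicate block gave 0 probes, as the blocked fit did. U87MG and T98G lay on slide 1 (4 arrays) and A172 on slide 2 (2 arrays), and the scan batch followed the slide. Each slide held both groups, and every knockdown array lay at the position after its control.

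The plan fixed before the data were examined was written for genes and for lists of genes. The files have no column of gene names, and no probe was given a gene from its identifier, so the gene-level results, HOTAIRM1 and the gene lists are not analysed here. The planned tests were run on probes, and the lists were replaced by classes read from the probe names, a choice made after the files were seen. Classes with at least 5 kept probes were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it. Several probes of a class can read the same RNA. The planned rule for named genes was used on probes. With 0 past the test, it takes probes above background on all 6 arrays that differed the same way in all lines, ranked by the smallest of the 3 differences. Because they have no gene names, it was limited to 2 in each direction. Control spots were mapped through each array's quantile function.

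The scripts were tested on simulated data for the comparison over 3 lines. Among 57367 simulated probes, limma recovered 0 of 67 changed by 1 on the log2 scale, 32 of 67 changed by 2 and 60 of 66 changed by 3, and it called 4 unchanged probes. In 20 simulated sets with no change, camera called 0 classes, under noise that was independent between probes.

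The alternatives were scaling by the 75th percentile over all probes or over those above background on all arrays, normexp background correction with an offset of 50, other filters, no block or slide as the block, leaving out each pair, trended and robust moderation, outlier spots kept, and thresholds of 1.5-fold and 3-fold. Normexp used the median signals because the files have no mean signal column.

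Some technical tests were chosen after values had been seen, as stated where they are reported. A comparison of rat- and mouse-named with human-named control spots was tried after the control spots had been seen, first as a replacement for the test of spots 5 and 3. It settled nothing either, so the earlier test was put back and the comparison is given as values. The test of small RNA yield was first read for all 3 lines from values of U87MG and T98G, and was then split so that A172 has its own value.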

Results

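RNA levels were measured on 6 one-colour Agilent long non-coding RNA arrays from 3 human glioma cell lines, U87MG, T98G and A172. In each line, cells stably transduced with short hairpin RNAs against HOTAIRM1, a long non-coding RNA transcribed from the HOXA gene cluster, were set against cells with a control hairpin. There were 3 knockdown and 3 control arrays, with 1 array per cell line and condition. The labels name no separate cultures beyond the lines, so the p-values of fry and of the exact test measure the spread between 3 lines. Those of single probes rest on that spread moderated by the spread of all kept probes. Camera sets the probes of a class against the other probes. Its p-values with the preset correlation therefore rest on the spread between probes, not between lines. The median processed signal was 153.12 in U87MG knockdown and 133.95 in its control, 97.119 and 93.895 in T98G, and 75.745 and 113.8 in A172. Between 75.02% and 81.71% of the probes were well above background on each array, the lowest share being that of the A172 knockdown array. The number of arrays limits the precision of every comparison. The files give probe identifiers without gene names, so HOTAIRM1 itself, and with it the strength of the knockdown, was not analysed here. The results therefore describe probe classes, unnamed probes, and the control spots named for GAPDH and PGK1.

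The first comparison asked which classes of transcripts differed after HOTAIRM1 knockdown over the 3 lines. Probes for small nucleolar and small Cajal body RNAs (snoRNA and scaRNA), which guide chemical modification of ribosomal and spliceosomal RNA, had a lower median signal after knockdown in each line. Among the 294 kept probes of this class, the median log2 difference was -0.17 in U87MG, -0.16 in T98G and -0.28 in A172, with a mean of -0.21 ± 0.065 (SD, n = 3 lines). This corresponds to a change of -13.2% in signal. In all 3 lines together, 121 of these probes (41.2%) were lower and 40 (13.6%) were higher, against 14.4% lower and 16.2% higher among all kept probes. The class passed limma's camera test with the preset correlation between probes (adjusted p = 5.89e-05). That call was lost with an estimated correlation (camera adjusted p = 0.802, unadjusted 0.128) and with fry (adjusted p = 0.694, unadjusted 0.161). Both rest on the 2 residual degrees of freedom of the fit, so the loss does not show that the class was unchanged. The adjusted 0.802 was the same for all 9 classes tested. Of the probes of this class, 0 passed when p was adjusted over the class alone. Within the slide that held U87MG and T98G, the class mean was -0.17 (adjusted p = 0.0173 with the preset correlation).

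The snoRNA and scaRNA probes did not move together in size. In A172, 24.5% of those measured were at least 2-fold lower and 0.69% at least 2-fold higher. In U87MG, 1.7% were at least 2-fold lower and 6.8% at least 2-fold higher, although the class median was below 0. In T98G these shares were 1.06% and 2.82%. Among all 55667 probes measured in A172, 5037 were at least 2-fold lower, as were 14.6% of transfer RNA probes and 14.6% of small nuclear RNA probes. The A172 knockdown array also had the lowest median signal (75.745) of the 6.

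Of the other small RNA classes, none had a median below 0 in all lines except the small nuclear RNAs (snRNA), the RNA parts of the splicing machinery. The 99 kept snRNA probes had medians of -0.11 in U87MG, -0.0077 in T98G and -0.17 in A172, and the class did not pass (camera adjusted p = 0.252). The 89 kept probes for transfer RNAs, which carry amino acids to the ribosome, had medians of 0.052, 0.061 and -0.14 in the same order (adjusted p = 0.543). The 13 kept ribosomal RNA probes had medians of -0.0016, -0.068 and 0.012 (adjusted p = 0.543).

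The probes named RNS, an abbreviation the files do not explain, had a higher median after knockdown mainly in A172. Their 1106 kept probes had medians of 0.02 in U87MG, -0.068 in T98G and 0.33 in A172, where that of all kept probes was 0.11. The mean of the RNS medians was 0.095 ± 0.211 (SD, n = 3 lines). The class passed camera narrowly (adjusted p = 0.0491). It did not pass with an estimated correlation (camera adjusted p = 0.802, unadjusted 0.681) or fry (adjusted p = 0.694, unadjusted 0.551). Without the A172 pair its mean was -0.024 (adjusted p = 0.745). The 819 kept imsncRNA probes, another unexplained name, had medians of -0.019, -0.076 and 0.21 and did not pass (adjusted p = 0.522). At 2-fold, 105 of these probes were lower and 7 higher in A172, 37 and 7 in U87MG, and 6 and 2 in T98G. Their mean of medians was 0.04 while the test pointed down. The 29932 kept A_ probes likewise had a mean of medians of 0.012 with a test pointing down (adjusted p = 0.522). The 24993 kept probes named by p and a number had a mean of 0.041 (adjusted p = 0.522), and the 16 kept probes named by RNA and a number did not pass either (adjusted p = 0.782). In all, 2 of 9 classes passed camera with the preset correlation and 0 with an estimated correlation.

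**Figure D1:**
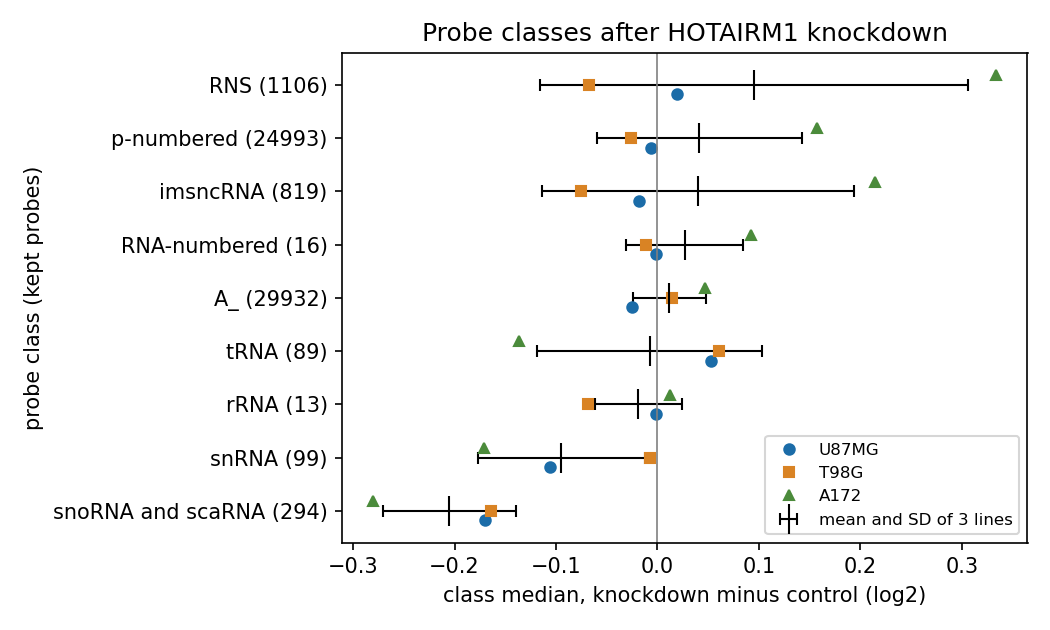
Median log2 difference, knockdown minus control, of each probe class on the horizontal axis, with 1 point per cell line and the mean and SD of the 3 lines in black. The snoRNA and scaRNA class lies below 0 in all 3 lines (-0.17, -0.16 and -0.28), while the RNS class lies at 0.33 in A172 and near 0 in the other lines.

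The control spots gave the only protein-coding genes named in the files. For PGK1, an enzyme of glycolysis, the spot numbered 3 differed by -0.75 (log2, knockdown minus control) in U87MG, 0.067 in T98G and 0.25 in A172, and the spot numbered 5 by -1.09, -0.37 and 0.13. The mean for spot 5 was -0.45 ± 0.615 (SD, n = 3 lines, exact two-sided sign-flip p = 0.5). The mean for spot 3 was -0.15 ± 0.532 (SD, n = 3 lines, exact two-sided sign-flip p = 1). For GAPDH, another glycolytic enzyme, spot 3 differed by -0.28, 0.18 and 0.48 (exact p = 0.75) and spot 5 by 0.041, 0.076 and -0.4 (exact p = 1). With 3 lines the exact test cannot give a p below 0.25. Scaling by the 75th percentile kept the sign of each PGK1 value except that of spot 3 in T98G, which became -0.034. For GAPDH spot 5 it turned U87MG to -0.13 and T98G to -0.033.

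**Figure D2:**
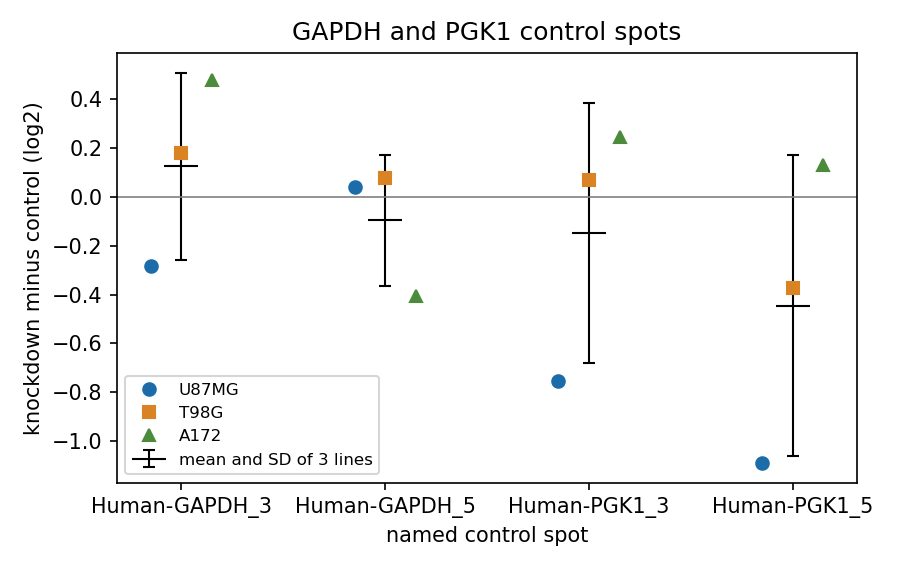
Log2 difference, knockdown minus control, of the control spots named for GAPDH and PGK1, with 1 point per cell line and the mean and SD of the 3 lines in black. PGK1 spot 5 lies at -1.09 in U87MG and at 0.13 in A172, so the lines spread widely around a mean of -0.45. After scaling by the 75th percentile, PGK1 spot 3 in T98G and GAPDH spot 5 in U87MG and T98G changed sign.

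The second comparison asked which single probes differed after knockdown over the 3 lines. Of 57367 kept probes, 0 passed an adjusted p of 0.05 in limma with cell line as a block, and the smallest adjusted p was 0.594. At an unadjusted p under 0.05 there were 4577 probes (7.98%), of which 1962 were higher and 2615 lower. The fit without the replicate block also gave 0 probes. Leaving out the U87MG pair gave 265 probes past the threshold and leaving out the T98G pair gave 6, while leaving out A172 gave 0.

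Among probes above background on every array, the 4 named here had the largest difference, within each direction, in the line where they differed least. None of the 4 passed the test (adjusted p = 0.594 each, limma). Each SE is limma's moderated one and not that of the 3 line differences alone. A_23_P301521 was 4.95-fold higher on average, with log2 differences of 2.49 in U87MG, 1.54 in T98G and 2.89 in A172 (mean 2.31, SE 0.297). The probe p21647 was 3.72-fold higher, with differences of 1.68, 1.44 and 2.57 (mean 1.9, SE 0.272). A_32_P202759 was 3.66-fold lower, with differences of -1.65, -1.56 and -2.41 (mean -1.87, SE 0.242). A_33_P3343155 was 3.39-fold lower, with differences of -1.88, -1.47 and -1.93 (mean -1.76, SE 0.204). Without the U87MG pair all 4 passed (limma adjusted p = 0.000777, 0.00283, 0.00288 and 0.0147), and without the T98G pair A_23_P301521 passed (adjusted p = 0.046). These probes were chosen for large differences in all 3 lines, so passing on part of the same lines is no separate support. The fit without U87MG also had 1 residual and 61.1 prior degrees of freedom, against 3.94 prior for all lines.

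Across all kept probes, 86 differed at least 2-fold in the same direction in all 3 lines, 37 higher and 49 lower. Of these, 55 were A_ probes (0.184% of the kept probes of that class) and 30 were probes named by p and a number (0.12%). The snoRNA and scaRNA class held 1 (0.34%), the highest share of any class. That probe was higher after knockdown, against the direction of the class median, but a share resting on 1 probe says little either way. When the sign of 1 line was turned, which leaves each line's sizes as they are, the count was 34 for U87MG, 31 for T98G and 34 for A172. With normexp background correction the count was 13. Among the 49674 probes well above background on all 6 arrays it was 43, against 86 among all 57367.

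The third comparison asked how alike the lines responded. Across the 57367 kept probes, which are not independent replicates, the log2 differences of U87MG correlated with those of T98G at Pearson's r = 0.189 (Spearman's rho = 0.234) and with those of A172 at r = 0.135 (rho = 0.156). The differences of T98G and A172 were close to uncorrelated, at r = 0.0078 (rho = -0.0058). U87MG and T98G shared a slide, and A172 lay on the other slide, so a value within a slide exists for that pair of lines alone.

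A172 had the most probes that differed at least 2-fold. There were 6671 of 55667 measured probes (12%) in A172, 3766 of 56737 (6.64%) in U87MG and 2604 of 56087 (4.64%) in T98G, with no replicate check within a line. In A172, 5037 of these were lower and 1634 higher, so 24.5% were higher. That share was 36.1% when arrays were scaled by their 75th percentile and 21% with normexp. It was 43.9% with the percentile taken over probes well above background on all arrays. There the median of all kept probes in A172 rose from 0.11 to 0.27. In U87MG, 2006 were higher and 1760 lower. In T98G, 1271 were higher and 1333 lower, a share of 48.8% higher that became 38.6% by the 75th percentile and 39.9% with normexp. In A172, 10.6% of A_ probes were at least 2-fold lower and 3.21% at least 2-fold higher, while for RNS probes the shares were 1.66% and 1.11%. The shares were 14.6% and 0% for tRNA, 14.6% and 4.17% for snRNA, and 13.1% and 0.871% for imsncRNA. For probes named by p and a number they were 7.17% and 2.79%.

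**Figure D3:**
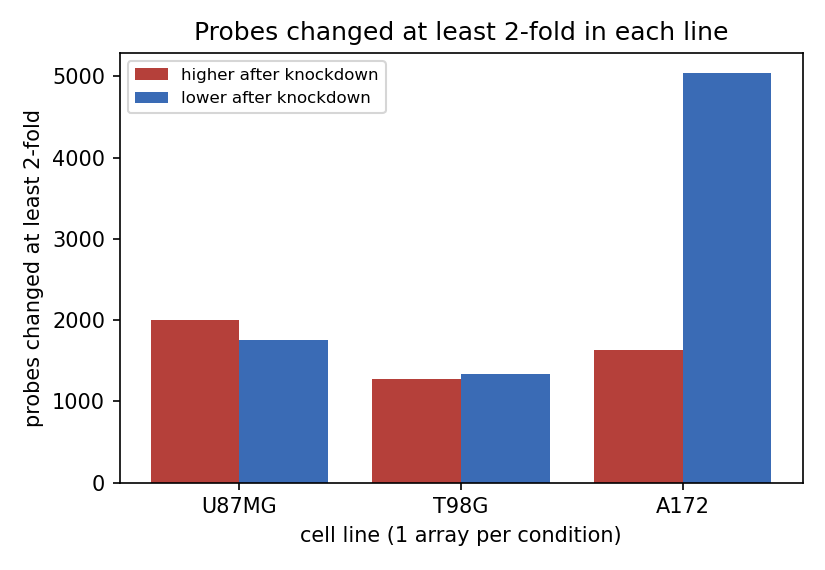
Number of probes that differed at least 2-fold between the knockdown and control array of each cell line, as bars from 0, with probes higher after knockdown beside those lower. A172 has 5037 lower and 1634 higher probes, U87MG 1760 and 2006, and T98G 1333 and 1271. The share of higher probes moved with the scaling, from 24.5% up to 43.9% in A172, from 53.3% up to 60.2% in U87MG and from 48.8% down to 38.6% in T98G. With normexp it was 21% in A172.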

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

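The tests of small RNA yield, of sample handling, of the shared slide and of array position were chosen after the values they bear on had been seen. Median log2 differences of 7 probe classes had opposite signs in different cell lines. With 1 array per line and condition, these differences between lines were not tested. The distance from the lowest to the highest line was 0.402 for RNS, 0.29 for imsncRNA, 0.197 for tRNA, 0.184 for probes named by p and a number, 0.104 for probes named by RNA and a number, 0.0803 for rRNA and 0.0718 for A_ probes. In the tRNA class A172 was the lowest line, and in every other class listed here it was the highest. The median of all kept probes in A172 was itself 0.11.

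The lower snoRNA and scaRNA signal was weighed first. Probe brightness is argued against, since 0 of 10000 lists matched on mean signal had a mean as low. The lists draw probes singly and lose any correlation between probes of a class, so the 0 may overstate the margin. The quantile step is argued against too, since relative to all kept probes the class stood at -0.248 with either 75th percentile in its place. With normexp it stood at -0.169. A constant per array shifts the class and all probes alike, so this measure cannot test the choice of such a constant. A lower yield of small RNAs stays open. In U87MG and T98G the median tRNA difference had a lower 95% bootstrap bound of 0.00191, which covers the spread between probes of single arrays and not between samples, while the snRNA medians were below 0 and the median tRNA level (log2) in T98G was 12.75 in knockdown against 12.85 in control. In A172 the median tRNA difference was -0.136, with a level of 10.8 against 11.96. The 10 splits of the 6 arrays are too few for a share under 0.05: the real split called 2 classes, 6 splits with the real one included called at least as many, and the highest other called 3. Splits that part the same pair alone are the same fit under the block. Those that part A172 alone are therefore counted more than once, and they restate the A172 difference. Of the 3 other splits that part all pairs, 2 also called the snoRNA and scaRNA class (adjusted p = 0.0369 and 0.000176). An effect of the knockdown on these RNAs may therefore be raised only as a hypothesis, which the estimated correlation (adjusted p = 0.802) does not carry.

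The larger number of 2-fold differences in A172 was weighed next. Noise between spots made up 7.13% of the excess over U87MG, and among the brightest 19123 kept probes the share at 2-fold was 2.48 times that of U87MG, so spot noise and dim probes are argued against as the whole cause. Handling or labelling of the A172 knockdown sample stays open: the change of GAPDH spot 5 minus spot 3 was -0.883 in A172, against 0.323 in U87MG and -0.102 in T98G, whereas for PGK1 it was -0.114, above both other lines. Before scaling, the 10 control probes named E1A had a median difference of -0.612 in A172, 0.0998 in U87MG and 0.29 in T98G. The 75th percentile of signal differed by -0.75, 0.134 and 0.0728 in the same order. After quantile normalization the E1A median was 0.116 in A172. With 1 array per condition these values do not settle the cause. A stronger response of A172 to the knockdown was not tested, because the line has 1 array per condition.

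The excess of probes at least 2-fold apart in the same direction in all lines (86, against 31 to 34 with a sign turned) was weighed last. For the U87MG correlations a trend with brightness or class is argued against, since the lower of them was 0.133 after such trends were removed. The correlation of T98G and A172 was near 0 both before (0.0078) and after (0.0095). The 86 and the counts with a sign turned were not taken again without the trends, so for these counts a trend stays open. The shared slide of U87MG and T98G stays open: of the pairs of lines on different slides, U87MG and A172 had r = 0.135 but T98G and A172 had r near 0, and the pair on 1 slide had the highest, r = 0.189. Array position cannot be told apart from knockdown, since the knockdown array followed its control in 3 of 3 pairs. For single probes the 10 splits are too few for a share under 0.05. The real split and the highest other split both gave 0 past the adjusted threshold, as did all 10, and at an unadjusted p under 0.05 the real split gave 4577, the highest other 9517, and 3 splits with the real one included at least as many. The 9517 came from parting the A172 pair alone, and the splits that do so are the same fit under the block, counted more than once. That fit sets the A172 difference against the spread of the other pairs and so restates its larger differences. Among the splits that part all pairs, the real one gave 4577 and the others 2655, 1920 and 1220.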

How the results depend on the processing

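Of the counts and correlations, 64 values held, as counts within 1.5 times or as correlations that moved by less than the SD of the 3 pairs of lines, and 26 moved. The T98G and A172 correlation, near 0 at 0.00777, has no settled sign, at -0.00129 with either 75th percentile and 0.0426 with normexp. The snoRNA and scaRNA class stayed past the threshold with the preset correlation under every alternative run (camera adjusted p from 2.83e-07 to 0.0173, the latter without A172). At the same median of -0.205 it did not pass with an estimated correlation or fry, where 0 classes passed. Both tests had been planned for the gene lists, and only the classes were chosen after the files were seen. The fit with no replicate block changed no call (0 probes, 2 classes). Filters of at least 1 array or none left 1 class. Normexp gave 13 probes in the same direction in all lines and 1497, 639 and 2967 at 2-fold in U87MG, T98G and A172, with the signal column, background method and offset changed together; the cause was not tested. Requiring all 6 arrays above background gave 43, with 2351 in U87MG and 1355 in T98G, from 49674 probes instead of 57367. These counts fell further in proportion than the number of probes did. The dropped probes, not above background on every array, therefore held more than their share of them. By construction, 1.5-fold gave 702 in the same direction and 10669, 8277 and 17854 per line, 3-fold gave 5 and 1161, 680 and 1976, and an unadjusted p gave 4577 probes.

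Leaving out 1 pair gave 0 to 265 probes past the threshold, 334 to 599 at 2-fold in the same direction (in 2 lines instead of 3), and 1 to 2 classes. The RNS class ran from -0.0241 without A172, a reversal, to 0.177 without T98G. The 265 came without U87MG, where the fit has 1 residual degree of freedom and estimated 61.1 prior degrees of freedom, against 3.94 for all lines. With the sign of A172 turned it called 0, and 182 of the 265 (68.7%) had the same sign in U87MG. The cause was not tested. Of the named probes, 47 values kept their side of the threshold and 5 passed it. The mean of the kept probes of a gene was not run, for want of gene names. Background limits the dim probes: 49674 of 71816 were well above it on all 6 arrays.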

Other observations

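The comparison of rat- and mouse-named spots was made after their values had been seen. The array carries control spots named for rat and mouse PGK1 and GAPDH besides the human ones. For PGK1 spot 5, the rat-named and mouse-named spots differed after knockdown by the same amount as the human-named spot in U87MG (0.048 and 0.02 apart on the log2 scale) and T98G (-0.034 and -0.014 apart). In A172 they were -1.73 and -1.63 apart. For GAPDH spot 5 the rat-named spot was 0.098 apart from the human-named one in U87MG, -0.15 in T98G and -0.23 in A172. The mouse-named spot was -0.053, -0.38 and 0.58 apart in the same order. So 3 of the 4 spots were lowest in A172, but only the PGK1 spots by a wide margin. These values come from 1 array per condition, and no explanation was tested with them.

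The 4 kept vault RNA probes had median log2 differences of 0.045 in U87MG, -0.26 in T98G and -0.38 in A172, too few for a class test.

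It was asked whether probes with consecutive p numbers read the same or neighbouring transcripts, a test set before its result was seen. Over 19096 consecutive pairs, their log2 differences correlated at r = 0.256 in U87MG, 0.206 in T98G and 0.193 in A172, against -0.0062, -0.011 and -0.003 for random pairs. The values lie between the bounds set for either answer, so the question stays open.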
